A study of Prunus persica with 12 samples.

How the data were processed

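RNA was measured in fruit mesocarp of 4 peach cultivars in 12 libraries, 2 for each of 6 groups, grouped by the cultivar, stage number and replicate number in the sample titles. RNA was extracted from frozen tissue and libraries were made by standard Illumina protocols, per the labels' protocols. The deposited values are RPKM per gene and library, per the file headers, in a separate table for each library with the same 27864 identifiers, 26110 beginning with ppa and 1754 with ppb. Bowtie 0.12.8, TopHat 1.4.0, HTSeq 0.5.3 and DESeq 1.10.1 are named in the submitters' processing notes, with no role or order. The genome build, the annotation, any filter and the handling of strand and of reads that match several genes are not given in the sources used here. Genes that share reads with a near-identical copy or overlap a neighbour are therefore uncertain. RPKM divides the reads of a gene by its length and by the depth of the library, so a gene that takes a larger share of a library lowers the RPKM of all others.

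The values were found to be whole multiples of what a single read is worth in each gene and library. From ratios of low values between libraries, the depth of each library and the length of each gene were worked back, with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. All 17316 genes above 0 in at least 2 libraries gave whole reads, for 100% of their values within 0.001 reads. The depths were 1942106 and 1205507 reads in HJ1, 2440928 and 3222252 in HJ2, 1814325 and 1470038 in HJ3, 2460741 and 2550536 in YL2, 1699524 and 1524800 in JX2, and 2505617 and 2889279 in ZH2. Reads of these genes made up between 99.976% and 99.997% of the depth. The median length was 1364 bp. Tested on simulated data with 5000 genes, the procedure returned all 12 depths and the right reads for 99.96% of 4930 genes. A value of 0 means that 0 reads were counted in a library, and an expected number of up to 3 reads was taken as possible there. For a gene of 1 kb, 3 reads are worth 0.931 RPKM in the deepest library and 2.49 RPKM in the shallowest. Intervals and floors cover counting error only.

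Comparisons used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), so a log2 difference is on that scale and understates the change of low genes. Genes with an RPKM of at least 1 in at least 2 libraries were kept, which left 15217. All 12 libraries entered a single fit with 6 group means and 6 residual degrees of freedom, with the empirical Bayes variance following the mean, so that groups of 2 libraries shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were the 3 pairs of HJ stages, the 6 pairs of cultivars at stage 2, the genes that set each cultivar apart from the other 3, and strong against slight aroma over the 6 group means. Overlaps of calls that share libraries were set beside the product of the shares of independent lists and beside 20 simulated data sets without any change between groups.

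The fit was tested on simulated reads for 14774 genes with a dispersion of 0.00612 and 100 genes changed at each of 2 fold sizes. The changed genes were drawn from those with a mean of at least 5 RPKM over the 12 libraries, so the shares called do not cover lower genes. For HJ2 against HJ1 it called 52% of the genes changed 2-fold and 92% of those changed 4-fold, with 8 false calls. For YL2 against HJ2 it called 45% and 88%, with 3 false calls. The simulated spread covers only what separates these replicate libraries.

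The tests of the comparisons named above, their groups and alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The measures of the transcript pool with their exact permutation test, and the counts of genes over both HJ steps, were not part of that plan. The rule took called genes whose libraries did not overlap between the groups compared and whose higher group had a mean of at least 10 RPKM, ranked by log2 difference (for genes that set a cultivar apart, by the smallest of the 3 differences). Without product names it allows at most 2 identifiers in each direction. The genes ppa012576m and ppa006857m fall outside it and were chosen after their values were seen. The reference gene table, of assembly Prunus_persica_NCBIv2, holds 26412 genes, and 0 of the 27864 identifiers matched it. The 21 planned gene lists, which search product names, were therefore not used, and their tests were not run. A fold against a group with 0 reads is a lower bound against 3 reads in its shallowest library, or in the shallowest of the other cultivars' libraries where all of those had 0 reads. With 1 to 3 reads, the ratio of depth-corrected reads is given with its exact 95% binomial interval. With more reads, the ratio of mean RPKM is given. The value of either ratio without a library is added where that moved it by over 1.5 times or left no reads to divide by.

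Alternatives were a pseudocount of 0.1, no filter, a filter of at least 5 RPKM in at least 2 libraries, rescaling of each library by the median ratio to the geometric mean of 11584 genes above 0 in all libraries, the replicate number as a block, leaving out each library in turn, and the aroma contrast in the fit of all 12 libraries. Added after the data had been seen were limma voom on the worked-back reads, depth counted without the reads of the 10 most abundant genes of each library, separate fits of HJ1 with HJ3 and of the 4 groups at stage 2, and a different HJ2 library for each HJ step. Median-ratio rescaling centres the differences between libraries, so a broad excess of higher or lower calls moves towards even whatever its cause. A balance already near even can move away from even. Reads worked back from RPKM gave no main result, since the unit of the files is RPKM. In the same simulated reads, with the same changed genes, voom called 73% and 94% of those changed 2-fold and 4-fold for HJ2 against HJ1, with 6 false calls. For YL2 against HJ2 it called 78% and 95%, with 14 false calls. For the comparison of genes detected at equal depth, reads were drawn without replacement down to 1205215 per library, 10 times. Exact tests used scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.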

Results

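Gene expression was profiled by RNA-seq in the mesocarp, the edible flesh, of peach (Prunus persica) fruit. The 12 libraries covered 4 cultivars in 6 groups, with 2 libraries per group. 'Hu Jing Mi Lu' (HJ) was sampled at 3 ripening stages, here HJ1, HJ2 and HJ3. 'Yu Lu' (YL2), 'Jin Xiu Huang Tao' (JX2) and 'Zhong Hua Shou Tao' (ZH2) were sampled at the stage numbered 2. The labels gave slight aroma for HJ1 and ZH2 and strong aroma for the other groups, and flesh that melts softly for all groups except ZH2, which was hard melting. Brix, a measure of soluble solids, was 12.1 in HJ2, 12.5 in HJ3, 14.9 in YL2, 12 in JX2 and 18 in ZH2, and was not given for HJ1. The series was designed around fruit softening and volatile compounds; firmness and volatile contents were not analysed here. The values were RPKM (reads mapped to a gene, per unit of gene length and of sequencing depth) for 27864 gene identifiers, of which 9413 were at 0 in all 12 libraries. Depth, worked back from the values, ran from 1205507 reads in the second HJ1 library to 3222252 reads in the second HJ2 library. Nothing in the labels says whether the libraries of a group came from separate fruit or trees, so p-values measure only the spread between these samples, which may be technical. The files did not pair identifiers with gene names, and 0 of the identifiers matched the reference gene table. Genes are therefore given by identifier, at most 2 higher and 2 lower for each comparison, with no function or position.

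The libraries of each group lay close together, and the groups lay apart. Pearson's r of log2(RPKM + 1) across genes was 0.961 for the pair of HJ1 libraries and 0.978 for the pair of HJ2 libraries, with the other pairs in between; these are correlations across genes, which are not independent replicates. In every pair the reads differed by more than sampling noise, with chi-square per degree of freedom of 1.75 (JX2) to 2.29 (HJ3). No pair therefore looked like a single library deposited a second time, which leaves open whether the pairs are repeat preparations of the same RNA. The leading principal component held 43.6% of the variance and ran from HJ1 through HJ2 to the remaining groups, and the next held 14.9%. The transcript pool was widest in HJ1. The 10 most abundant genes took 16.3% ± 0.437 of the RPKM sum in HJ1, 24.0% ± 0.0938 in HJ2 and 29.1% ± 1.14 in HJ3 (mean ± SD, n = 2). In the other cultivars they took 27.5% ± 0.730 (YL2), 30.9% ± 0.531 (JX2) and 32.4% ± 0.353 (ZH2). The effective number of genes, the exponential of the Shannon entropy of the RPKM shares, was 1948 ± 44.7 in HJ1, 1131 ± 14.2 in HJ2 and 896 ± 71.1 in HJ3 (SD, n = 2). The groups differed in both measures by an exact permutation test over all 10395 ways to part the 12 libraries into 6 pairs. The exact p was 9.62e-05 for the share of the 10 genes, the smallest the test can give, and 0.000673 for the effective number, with Benjamini-Hochberg values of 0.000192 and 0.000673 over both. This test was not part of the plan fixed beforehand. It covers the 6 groups together, and for a single pair of groups an exact two-sided p cannot go below 0.333.

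**Figure D1:**
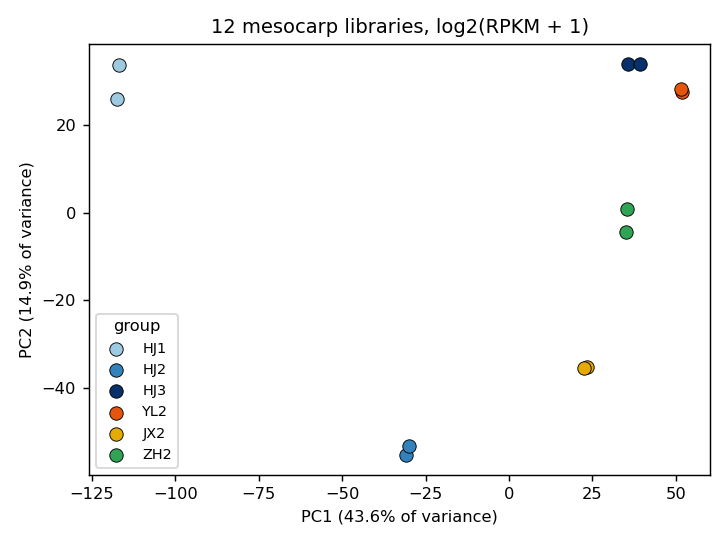
Principal components of log2(RPKM + 1) over 15217 genes, with 1 point per library coloured by group. The horizontal axis holds 43.6% of the variance and separates HJ1, at scores near -117, from HJ3, at 35.7 and 39.3, with HJ2 between them.

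**Figure D2:**
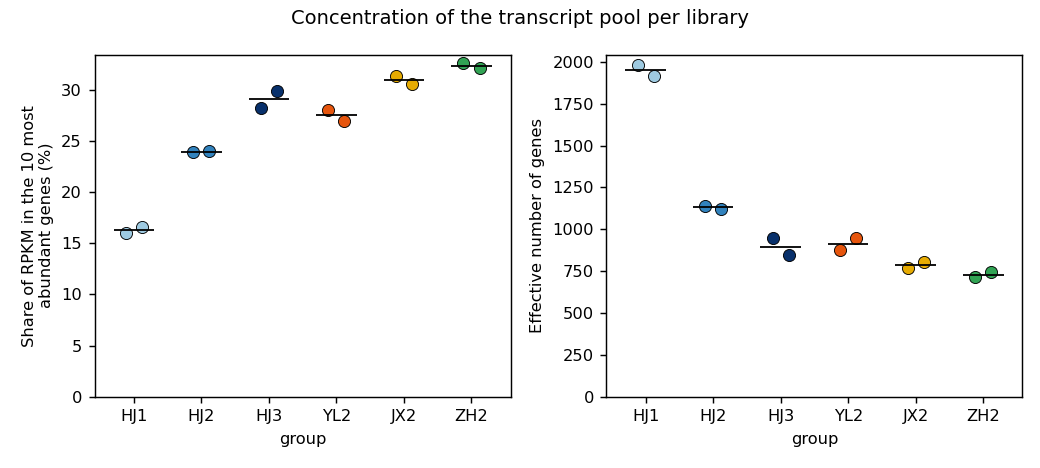
Share of the RPKM sum held by the 10 most abundant genes of each library (left, percent) and effective number of genes (right). Points are libraries and lines are group means; both HJ1 libraries lie below all others on the left and above all others on the right.

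The abundant gene ppa012576m, singled out after its values were seen, had the highest mean RPKM over the 12 libraries. Its RPKM was 45395 ± 2918 in HJ1, 85742 ± 1088 in HJ2 and 94325 ± 1701 in HJ3 (SD, n = 2), which was 5.74%, 11.3% and 13.1% of the RPKM sum. It rose from HJ1 to HJ2 by a log2 change of 0.92 ± 0.0982 (SE, limma adjusted p = 3.90e-05). From HJ2 to HJ3 the log2 difference was 0.14 ± 0.0982, with a limma adjusted p of 0.336. Rescaling each library by its median ratio moved the median log2 difference of all genes up by 0.15 for HJ2 against HJ1, 0.16 for HJ3 against HJ2 and 0.32 for HJ3 against HJ1. The shift was 0.15 for YL2, 0.13 for JX2 and 0.20 for ZH2, each against HJ2. Rescaling centres the differences, so a broad excess of higher or lower calls is drawn towards even whatever its cause. A balance already near even could move away from it. The share of higher calls went from 49.0% to 54.9% for ZH2 against YL2 and from 46.2% to 56.5% for ZH2 against JX2. For JX2 against YL2 it went from 52.1% to 49.9%. Counts after rescaling are given where they move the balance of higher and lower calls by over 10 percentage points.

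The step from stage 1 to stage 2 in HJ was examined for genes that change early in ripening. The gene ppa011478m rose from an RPKM of 4.52 ± 2.82 in HJ1 to 1539 ± 78.0 in HJ2 (SD, n = 2), a ratio of 340, with a log2 change of 8.22 ± 0.253 (SE, limma adjusted p = 4.08e-09). The HJ1 level rests on 13 reads, and the ratio was 609 without HJ1 replicate 2. The gene ppa011307m rose from 3 reads, all in a single HJ1 library, to an RPKM of 1258 ± 100.4 in HJ2. Its depth-corrected ratio of reads was 1265 (95% counting interval 433 to 6135), or 484 without HJ1 replicate 1, with no ratio without HJ1 replicate 2, which held all 3 reads, and limma gave an adjusted p of 0.000124. The gene ppa013282m fell from 1036 ± 207 RPKM in HJ1 to 3 reads in HJ2, a ratio of 1271 (434 to 6170) and a limma adjusted p of 2.56e-08. The gene ppa014189m stood at 124 ± 9.27 RPKM in HJ1 and had 0 reads in HJ2, so that it was at least 31.4-fold lower (limma adjusted p = 1.28e-08). It also had 0 reads in HJ3, YL2, JX2 and ZH2. Of 15217 genes tested with limma, 4574 passed an adjusted p of 0.05, and 1251 of them were higher and 3323 lower in HJ2. After rescaling, 1645 were higher and 2556 lower, so the share of higher calls moved from 27.4% to 39.2%; with depth counted without the 10 most abundant genes of each library, an alternative added after the data had been seen, the numbers were 1572 and 2620. A log2 difference of at least 1 was reached by 696 of the higher and 2312 of the lower calls.

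The step from stage 2 to stage 3 gave a different pair of leading genes in each direction. The gene ppa014623m had 0 reads in HJ2 and 68.0 ± 0.783 RPKM in HJ3 (SD, n = 2), at least 53.8-fold higher (limma adjusted p = 4.84e-07). The gene ppa008439m rose from 1.49 ± 0.691 RPKM, on 10 reads, to 158 ± 33.2 RPKM, a ratio of 107 (95% counting interval 61.3 to 238, limma adjusted p = 9.38e-08). Their HJ1 values were 4.58 ± 1.98 and 15.5 ± 4.42 RPKM. The gene ppa013018m fell from 112 ± 19.9 RPKM in HJ2 to 3 reads in HJ3, a ratio of 93.2 (95% counting interval 31.7 to 453), and ppa006496m fell from 47.4 ± 3.25 RPKM to 2 reads, a ratio of 126 (34.5 to 1040). The reads of each lay in a single HJ3 library: the ratios were 41.7 without HJ3 replicate 1 and 69.4 without HJ3 replicate 2, and the other library left out gave no ratio. Their limma adjusted p-values were 2.83e-06 and 5.31e-07. Among all genes tested, limma called 4480, with 1623 higher and 2857 lower in HJ3. After rescaling the balance was 2069 higher and 2046 lower. With depth counted without the 10 most abundant genes it stayed on the lower side, at 1769 and 2484. Limma voom on whole reads, also added after the data had been seen, gave 1886 and 2883. Voom was scaled by total reads, as RPKM is, so it is no check on a shift from abundant genes. In the main fit, 625 genes of the longest tertile were higher and 605 lower. Without the HJ2 library of replicate 1 the count was 2881.

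Between the outer stages, HJ3 against HJ1, the changes were the most numerous of the 9 pairwise comparisons. The gene ppa011478m reached 4057 ± 411 RPKM in HJ3 (SD, n = 2), a ratio of 897 to HJ1, or 1604 without HJ1 replicate 2 (log2 change 9.62 ± 0.253 SE, limma adjusted p = 7.01e-10). The gene ppb020940m had 0 reads in HJ1 and an RPKM of 641 ± 2.92 in HJ3, at least 112-fold higher (limma adjusted p = 2.42e-12). It stood at 142 ± 10.2 RPKM in HJ2 and at 1259 ± 159 RPKM in ZH2. The gene ppa006620m fell from 2041 ± 44.9 to 3.35 ± 0.925 RPKM, a ratio of 610 and a log2 change of -8.89 ± 0.179 (SE, limma adjusted p = 8.41e-11). The gene ppa013282m was down to a single read in HJ3, a ratio of 2212 with a counting interval of 397 to 87414, or 1222 without HJ3 replicate 2, and with no ratio without the library that held the read. In total limma called 6544 genes, 1598 higher and 4946 lower, of which 999 and 3505 had a log2 difference of at least 1. After rescaling, 2531 were higher and 3282 lower, moving the share of higher calls from 24.4% to 43.5%. With depth counted without the 10 most abundant genes, 2074 were higher and 3782 lower. In a fit of the HJ1 and HJ3 libraries alone, also added after the data had been seen, limma called 4361 genes.

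**Figure D3:**
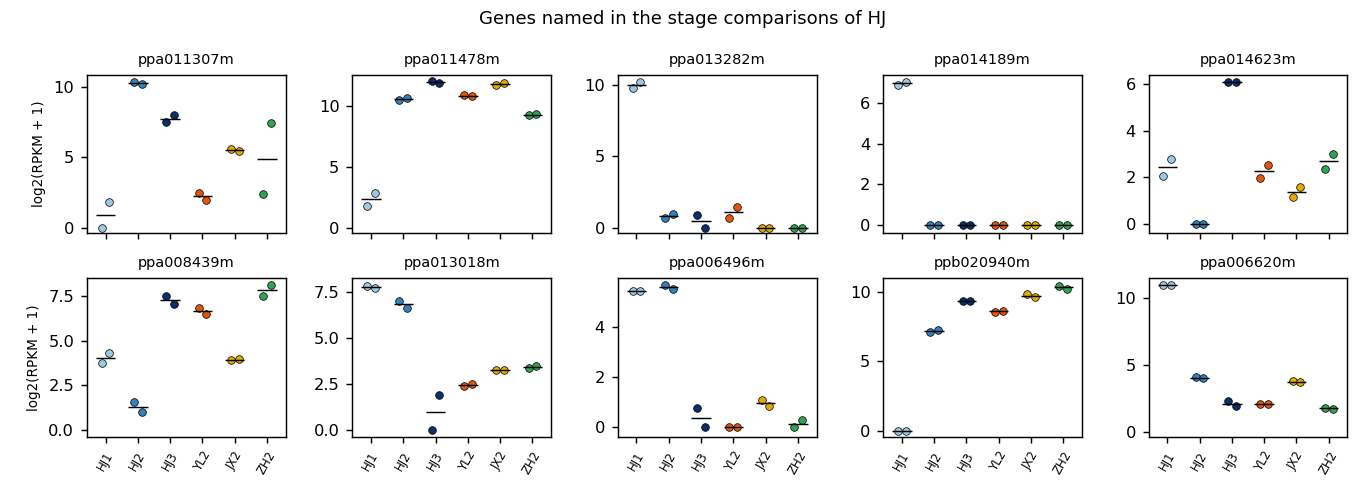
log2(RPKM + 1) of the 10 genes named in the stage comparisons, with 1 point per library, lines at the group means and groups on the horizontal axis. The gene ppa011478m climbs from HJ1 to HJ3, whereas ppa014189m has reads in HJ1 and 0 reads in the 5 other groups.

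Across both HJ steps, reversals were common. These counts were not part of the plan fixed beforehand. Of the 15217 genes tested, 771 fell from stage 1 to stage 2 and rose from stage 2 to stage 3, where independent lists would share 354.4, and 544 rose and then fell, where independent lists would share 235. A fall at both steps was found for 691 genes (624 for independent lists) and a rise at both for 162 (133 for independent lists). After rescaling, 752 genes fell and then rose, 519 rose and then fell, 440 fell at both steps and 251 rose at both. Simulated unchanged groups gave 0 genes in each of these 4 patterns in 20 draws; with no real differences and a mean of 0.122 genes called per comparison, that sets no level for the overlap of real changes. Both steps share the HJ2 libraries, so part of the excess of reversals may come from them. The count was therefore repeated, after the data had been seen, with a different HJ2 library for each step, in both arrangements. Of 15085 genes, 512 and 509 then fell and rose (191 and 189.5 for independent lists), and 278 and 268 rose and fell (97.8 and 98.4). A fall at both steps was found for 390 and 388 genes (274 and 283), and a rise at both for 111 and 118 (68.2 and 65.8). These steps share no library, but each rests on a single HJ2 library, and both use the spread estimated from the other groups. A deviation common to both HJ2 libraries would remain, so the split cannot remove it. All 4 patterns exceeded independent lists, reversals by more than changes in the same direction. An excess over independent lists alone therefore does not single out reversals.

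The cultivars were compared pairwise at stage 2, which the labels number alike without giving how ripe the fruit were. Against HJ2, limma called 4845 genes in YL2 (1751 higher, 3094 lower), 3785 in ZH2 (1213 higher, 2572 lower) and 2515 in JX2 (809 higher, 1706 lower). After rescaling, the numbers higher and lower were 2237 and 2388 in YL2, 1697 and 1637 in ZH2, and 1030 and 1163 in JX2. With depth counted without the 10 most abundant genes, which does not centre the differences, more genes stayed lower, with 1891 higher and 2771 lower in YL2, 1431 and 2015 in ZH2, and 960 and 1311 in JX2. Limma voom, scaled by total reads as RPKM is and so no check on this shift, gave 1514 higher and 3532 lower in ZH2. JX2 differed from YL2 at 3641 genes (1897 higher, 1744 lower), ZH2 from YL2 at 2825 (1384 higher, 1441 lower), and ZH2 from JX2 at 2520 (1163 higher, 1357 lower). The balance of these 3 comparisons was near even and changed sides with rescaling, to 1849 higher and 1853 lower for JX2 against YL2, 1598 and 1312 for ZH2 against YL2, and 1479 and 1138 for ZH2 against JX2. Depth counted without the 10 most abundant genes gave 2092 and 1614, 1603 and 1260, and 1251 and 1322, so only ZH2 against YL2 changed sides there. Leaving out a library moved 5 of these 6 counts by over 1.5 times, always downwards. JX2 against HJ2 fell to 1241 and 1459 without HJ2 replicates 1 and 2, and ZH2 against HJ2 to 2353 and 2439 without them and to 2415 without ZH2 replicate 2. JX2 against YL2 gave 2357 and 2361 without YL2 replicates 1 and 2. ZH2 against YL2 gave 1799 without YL2 replicate 2, and 1871 and 1771 without ZH2 replicates 1 and 2. ZH2 against JX2 gave 1446 and 1463 without ZH2 replicates 1 and 2.

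**Figure D4:**
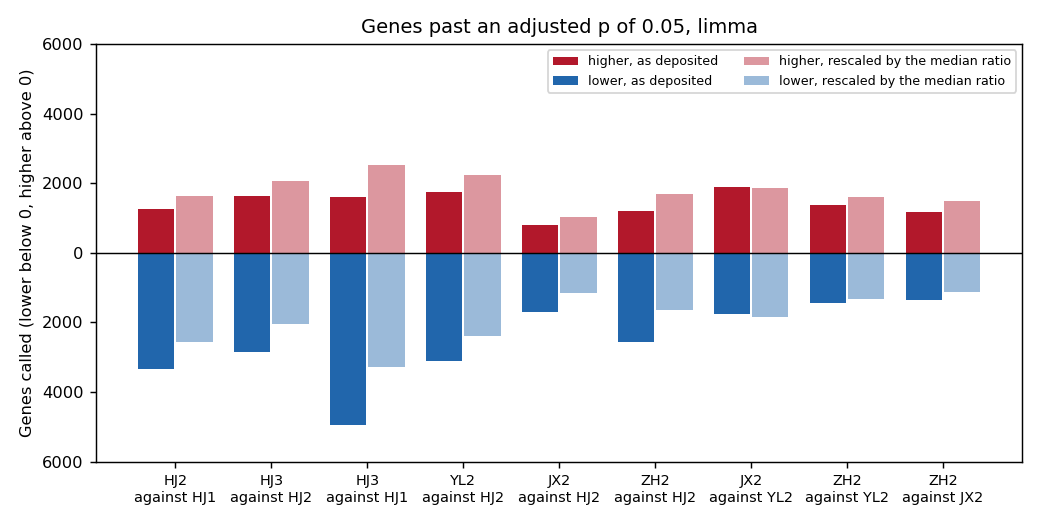
Number of genes called by limma in each of the 9 pairwise comparisons, higher above 0 and lower below 0, as deposited (dark) and after median-ratio rescaling (pale). HJ3 against HJ1 has the most lower calls, 4946 as deposited and 3282 after rescaling.

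A gene set a cultivar apart when it was called in the same direction against each of the other 3 at stage 2. HJ2 was set apart by 1205 genes, 839 higher and 366 lower. Of these, 618 of the higher genes fell from HJ1 to HJ3 and 241 of the lower genes rose. The list may therefore reflect stage as well as cultivar, which cannot be told apart here. The gene ppa014027m stood at 33.8 ± 1.51 RPKM in HJ2 (SD, n = 2) and had 0 reads in YL2, JX2 and ZH2, at least 9.28-fold higher; the highest of its 3 limma adjusted p-values was 4.61e-06. It stood at 46.6 ± 13.7 RPKM in HJ1 and had a single read in HJ3. The gene ppa011307m, at 1258 ± 100.4 RPKM in HJ2, was 14.2 times ZH2, the nearest cultivar by mean RPKM, whose libraries stood at 4.13 and 173 RPKM, so that the ratio was 7.25 or 304 with either left out. On the log2 scale JX2 was nearest, at a difference of 4.76 (highest limma adjusted p = 0.0183). This call was lost when any single HJ2 or JX2 library was left out (log2 4.68 to 4.84, from JX2) and at a pseudocount of 0.1 (log2 4.79). ZH2 minus HJ2 was -5.39 on the log2 scale with all libraries, and without ZH2 replicate 1 ZH2 became the nearest, at a difference of 2.85. The gene ppa024380m had 0 reads in all 6 HJ libraries and stood at 98.1 ± 8.92 RPKM in YL2, 61.1 ± 4.58 in JX2 and 94.0 ± 3.92 in ZH2, so that HJ2 was at least 54.1-fold lower (highest limma adjusted p = 2.76e-08). The gene ppa010796m was at 1.86 ± 1.04 RPKM in HJ2 and 60.3 ± 7.79 in JX2, the nearest cultivar, a ratio of 32.5, or 53.7 without HJ2 replicate 1 (highest limma adjusted p = 4.02e-07), and reached 155 ± 11.2 RPKM in HJ3. After rescaling, 545 genes were higher and 479 lower in HJ2, and with depth counted without the 10 most abundant genes 639 of 1068 were higher. The total was 639 without HJ2 replicate 1 and 715 without HJ2 replicate 2.

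YL2 was set apart by 1307 genes, 663 higher and 644 lower. The gene ppa1027191m stood at 165 ± 28.6 RPKM in YL2 (SD, n = 2) and 2.49 ± 1.61 in JX2, a ratio of 66.1, with 0 reads in HJ2 and ZH2. The JX2 level rests on 4 reads, with a 95% counting interval for the ratio of 24.9 to 237 (highest limma adjusted p = 9.27e-07). Without JX2 replicate 1, which leaves a single read, the ratio was 122 (21.7 to 4819). The gene ppb022522m stood at 44.0 ± 4.17 RPKM in YL2 and had 0 reads in HJ2, JX2 and ZH2, at least 5.98-fold higher (highest limma adjusted p = 6.56e-06). The gene ppa027232m was lower in YL2, at 2.77 ± 1.25 RPKM against 82.2 ± 10.1 in ZH2, the nearest cultivar, a ratio of 29.6 (highest limma adjusted p = 8.40e-08). Its YL2 level rests on 6 reads, with a 95% counting interval for the ratio of 13.2 to 80.7. The gene ppa008481m had 0 reads in YL2 and 20.6 ± 4.15 RPKM in JX2, the nearest cultivar, at least 19.4-fold lower (highest limma adjusted p = 2.43e-07). Of these genes, ppa008481m was also low in HJ3, at 1.07 ± 0.159 RPKM, against 101 ± 1.32 in HJ1. The total was 862 without YL2 replicate 1 (44.8% higher) and 814 without YL2 replicate 2 (43.5% higher). The balance was near even and turned to more lower genes there and at a pseudocount of 0.1, with 45.5% of 1242 higher, and with depth counted without the 10 most abundant genes, with 44.8% of 1338.

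JX2 was set apart by the fewest genes, 314, with 136 higher and 178 lower. The gene ppa006109m stood at 4.45 ± 2.27 RPKM in JX2 (SD, n = 2) against 899 ± 43.4 in ZH2, 1087 ± 124 in HJ2 and 1842 ± 54.2 in YL2, 202 times lower than in ZH2, or 317 times without JX2 replicate 1 (highest limma adjusted p = 2.42e-08). The gene ppa010379m was at 5.13 ± 1.59 RPKM in JX2 and 59.6 ± 6.52 in ZH2, a ratio of 11.6 (highest limma adjusted p = 8.96e-06). The gene ppa018303m stood at 86.4 ± 0.863 RPKM in JX2 and, on 7 reads, at 1.499 ± 0.449 in ZH2. The ratio was 57.7 (95% counting interval 28.0 to 147, highest limma adjusted p = 1.29e-06), and the gene had 0 reads in HJ2. The gene ppa024445m stood at 31.7 ± 4.91 RPKM in JX2, had a single read in YL2 and in ZH2, and gave a ratio of 56.0 to YL2 (95% counting interval 9.42 to 2271, highest limma adjusted p = 4.21e-05). The ratio was 27.5 without YL2 replicate 2, and the other YL2 library left out gave none. Both genes that were higher in JX2 also had reads in HJ3, at 39.6 ± 3.44 and 9.48 ± 0.188 RPKM. Limma voom on whole reads, an alternative chosen after the data had been seen, turned the balance, with 201 genes higher and 153 lower, and so did depth counted without the 10 most abundant genes, with 149 of 292 higher. At a pseudocount of 0.1 the share of higher genes was instead 32.8% of 323, and without JX2 replicate 2 it was 30.7% of 231. The total was 170 and 195 without HJ2 replicates 1 and 2, and 197 without ZH2 replicate 1.

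ZH2, the hard-melting cultivar, was set apart by 583 genes, 288 higher and 295 lower. The gene ppa005455m stood at 109.5 ± 20.7 RPKM in ZH2 (SD, n = 2) and had 3 reads in JX2, the nearest cultivar, a ratio of 161 (95% counting interval 54.95 to 783, highest limma adjusted p = 2.98e-07), or 255 without JX2 replicate 2. The gene ppa016653m stood at 36.4 ± 9.97 RPKM in ZH2 and had a single read in JX2 and in HJ2, a ratio of 72.3 to JX2 (12.7 to 2880, highest limma adjusted p = 1.59e-05), or 34.2 without JX2 replicate 1, and with no ratio without JX2 replicate 2, which held the read. The gene ppa009649m had 0 reads in ZH2 and 463 ± 63.6 RPKM in HJ2, 328 ± 15.3 in JX2 and 106 ± 2.93 in YL2, so that ZH2 was at least 99.9-fold lower than YL2 (highest limma adjusted p = 1.06e-10). The gene ppa014179m had 0 reads in ZH2 and 159 ± 44.3 RPKM in YL2, the nearest cultivar, at least 81.5-fold lower (highest limma adjusted p = 2.07e-09). The balance was near even, and after rescaling 383 genes were higher and 214 lower. With depth counted without the 10 most abundant genes, 332 of 582 were higher. At a pseudocount of 0.1 the share of higher genes was instead 40.2% of 565. The total was 345 without ZH2 replicate 1 and 325 without ZH2 replicate 2.

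The 3 comparisons behind each of these lists share the libraries of the cultivar in question. Independent lists would set HJ2 apart by 58.6 higher and 7.42 lower genes, YL2 by 19.0 and 35.1, JX2 by 8.99 and 14.9, and ZH2 by 8.43 and 21.7. Simulated unchanged groups gave 0 genes set apart in 20 draws, but with a mean of 0.122 genes called per comparison they could hardly give any, so this value sets no level for overlap among real differences. Part of the excess over independent lists may come from the shared libraries.

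**Figure D5:**
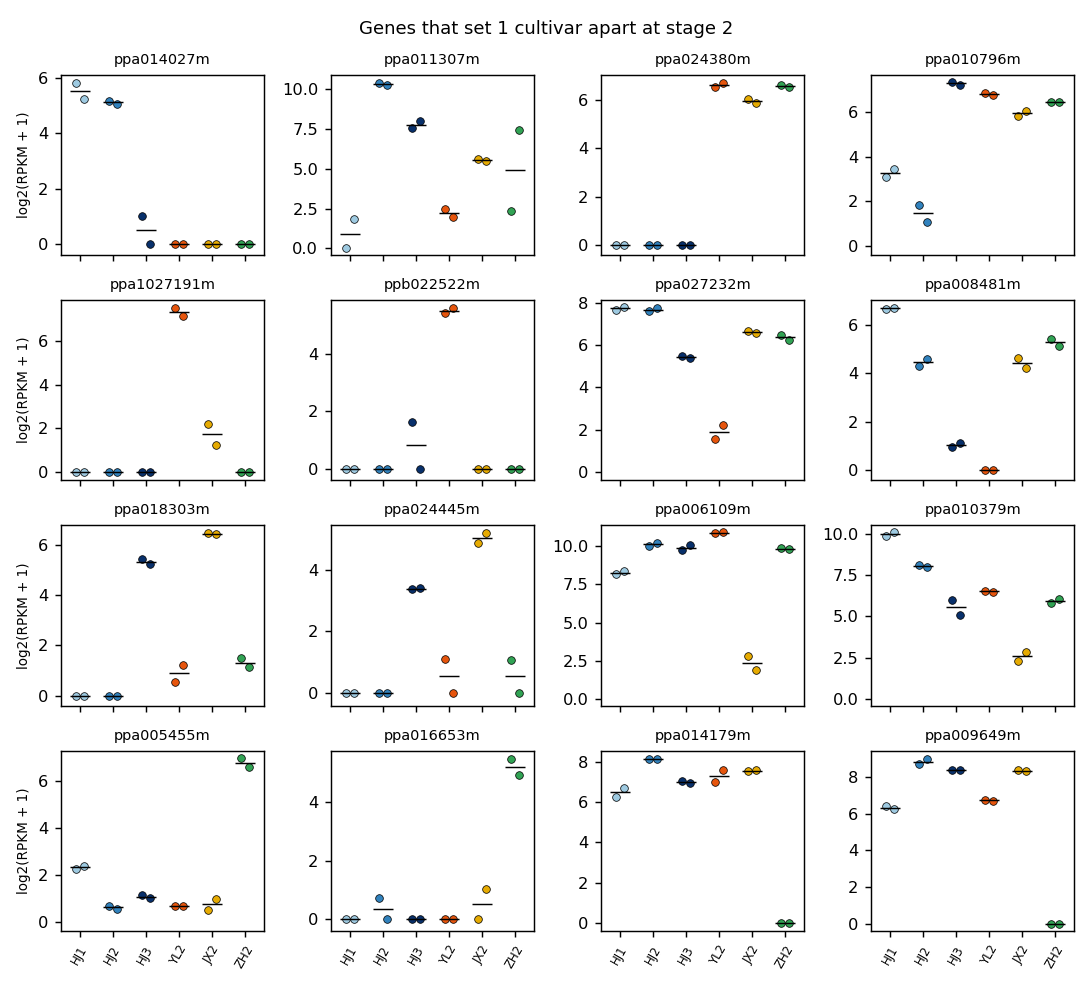
log2(RPKM + 1) of the 16 genes named for setting a cultivar apart at stage 2, in rows for HJ2, YL2, JX2 and ZH2, with 1 point per library and lines at the group means. In the bottom row, ppa014179m and ppa009649m lie at 0 in both ZH2 libraries and above 6 in every library of the other groups.

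Aroma strength was compared over group means, since a label shared by several groups has the group as its replicate. HJ1, HJ2 and HJ3 are the same cultivar, so even the groups are not independent samples of aroma. The slight groups are the only stage 1 group and the only hard-melting cultivar. Aroma cannot be told apart from these. Between the 4 groups with strong and the 2 with slight aroma, limma called 0 genes, and the lowest adjusted p was 0.854. With so few group means, this does not show that no gene goes with aroma. An unadjusted p under 0.05 was found for 628 genes, where chance gives 761. Limma voom on whole reads also called 0 genes. The gene with the lowest unadjusted p, ppa006857m, singled out after its values were seen, stood at 0.314 ± 0.444 RPKM in HJ1 and 0.649 ± 0.574 in ZH2 (SD, n = 2). In the strong groups it stood at 70.5 ± 0.542 (HJ2), 559 ± 26.1 (HJ3), 829 ± 14.4 (YL2) and 202 ± 17.3 (JX2). Its strong minus slight log2 difference was 7.65 ± 0.936 (SE over group means) and did not pass the adjustment, at 0.854. Fitted over all 12 libraries as if each were a replicate of its label, limma called 4729 genes for the same contrast, 1359 higher and 3370 lower with strong aroma; that count treats the libraries of a group as independent samples of the aroma label.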

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

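All 14 counts (9 pairwise comparisons, 4 set-apart lists and aroma) stayed within 1.5 times under a pseudocount of 0.1, no filter, the filter of 5 RPKM, rescaling and, added after the data had been seen, limma voom and depth without the 10 most abundant genes. In separate fits of HJ1 with HJ3 and of stage 2, also added later, HJ3 against HJ1 fell to 4361, with fewer samples for the spread, and the 4 set-apart counts stayed within 1.5 times. The aroma contrast in the fit of all 12 libraries was a further exception, with 4729 genes against 0; by construction it counts 12 libraries as replicates in place of 6 groups. The balance of higher and lower genes was near even, and changed sides in some settings, for JX2 against YL2, ZH2 against YL2, ZH2 against JX2 and the lists of YL2 and ZH2; in the list of JX2 higher genes made up 43.3%, and from 30.7% to 56.8% over the settings. No named gene reversed. In 28 values per setting, 1 lost its call at a pseudocount of 0.1 and 0 in the other settings, and of 174 values with a library left out 4 did; all 5 belong to ppa011307m as a gene that sets HJ2 apart. The gene ppa014189m, read in HJ1 alone, fell below the filter without either HJ1 library and gave no value there. Leaving out each library in turn moved 22 of 80 counts by over 1.5 times, all downwards, with fewer samples and a lone library that is assumed to vary like the other groups. The lowest and highest counts were 3148 and 3410 for HJ2 against HJ1, 2881 and 3851 for HJ3 against HJ2, 5000 and 5817 for HJ3 against HJ1, 3272 and 3415 for YL2 against HJ2, 1241 and 1782 for JX2 against HJ2, and 2353 and 2533 for ZH2 against HJ2. They were 2357 and 2741 for JX2 against YL2, 1771 and 1890 for ZH2 against YL2, and 1446 and 1793 for ZH2 against JX2. For genes set apart they were 639 and 1036 in HJ2, 814 and 1153 in YL2, 170 and 231 in JX2, and 325 and 482 in ZH2. Aroma stayed at 0. The planned tests of gene lists were not run, because identifiers could not be matched to product names, nor were the count models planned for deposited whole-number counts, because the files hold RPKM. Depth limits genes of a few reads most, and a count of 0 does not show absence.

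The replicate numbers did not pair the samples. The correlation of deviations between same-numbered libraries, over 15 pairs of groups, ran from -0.0667 to 0.0499 with a median of 0.00496. With a replicate block, HJ2 against HJ1 gave 4429 genes and HJ3 against HJ1 gave 6439, and none of the 13 counts with such a fit moved by over 1.5 times.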

Other observations

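The tests of the balance of calls with another depth, gene length, depth, sequence difference and position along the HJ stages were chosen after the results they bear on had been seen, and so was the counting-error requirement in the test of a graded fall. The tests of genes detected and of the effective number without the 10 most abundant genes were written before their own values were seen, but after those with all genes.

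The genes that set cultivars apart at stage 2 overlapped with those that changed between HJ1 and HJ3. The libraries compared are not shared, but the fit is, so both sets of calls rest on the same estimate of spread per gene and are not independent. Of the 839 genes higher in HJ2 than in the other 3 cultivars, 618 fell from HJ1 to HJ3, where independent lists would share 273, and 50 rose, where they would share 88.1. Of the 366 lower in HJ2, 241 rose (38.4 for independent lists) and 34 fell (119). After rescaling, 68.4% of the genes higher in HJ2 fell from HJ1 to HJ3, against 21.6% of all genes tested, and 73.5% of those lower in HJ2 rose, against 16.6%. In YL2, 416 of the 644 lower genes fell (209 for independent lists) and 72 rose (67.6), and of its 663 higher genes 208 rose (69.6) and 192 fell (215). In JX2, 89 of the 178 lower genes fell (57.9) and 30 rose (18.7), and of its 136 higher genes 57 rose (14.3) and 25 fell (44.2). In ZH2 the 295 lower genes split into 106 that fell (95.9 for independent lists) and 69 that rose (30.98), and its 288 higher genes into 89 that fell (93.6) and 85 that rose (30.2). Rising genes thus exceeded independent lists in both directions in ZH2 and in JX2. Independent lists take every gene as equally likely to be called, here and in the separate fits that follow, which was not tested. An excess in both directions therefore need not be a link with the HJ stages. Fits of HJ1 with HJ3 and of stage 2 made separately, which share no estimate of spread, gave 544 of 911 genes higher in HJ2 that fell (198 for independent lists) and 191 of 359 lower that rose (24.9). They also gave 349 of 665 genes lower in YL2 that fell (144). Genes that rose were 69 of 295 higher (20.5) and 48 of 311 lower (21.6) in ZH2, and 43 of 157 higher (10.9) and 26 of 192 lower (13.3) in JX2. These are counts across genes, which are not independent replicates.

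On a scale set by the 1598 rising and 4946 falling genes, with HJ1 at 0% and HJ3 at 100%, HJ2 stood at 43.7% ± 0.344, JX2 at 68.5% ± 0.598, ZH2 at 71.8% ± 1.89 and YL2 at 79.4% ± 0.453 (SD, n = 2). Rescaling gave 42.5%, 67.7%, 71.4% and 78.9%. HJ2 stood lowest of the cultivars at stage 2, so its differences from the others may reflect position along the stages as well as cultivar. The hypothesis that ZH2 fruit were less advanced along this scale was tested against each cultivar, as both ZH2 libraries lying below both of the other's with a mean difference above the larger SD. Against YL2 they did, with a mean difference of -7.61 percentage points, so ZH2 may have been less advanced than YL2. Against JX2 both ZH2 libraries lay above, by 3.26 points on average, the opposite of the hypothesis on this scale. The rule restates the positions given above and adds no separate evidence. A position on genes chosen in HJ cannot tell ripeness from a difference of cultivar. The scale reads transcripts that change in HJ and does not measure firmness, and 2 libraries against 2 allow no exact two-sided p below 0.333.

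More genes were lower than higher in HJ3 against HJ1. A trend with gene length is not the whole cause, since 66.0% of the calls were lower even in the longest tertile of genes; a trend was present, with median log2 differences of -0.66 in the shortest tertile and -0.20 in the longest. This does not extend to HJ3 against HJ2, where 72.6% of the calls were lower in the shortest tertile and 49.2% in the longest, so the excess at that step lay in the shorter genes and a trend with length is not excluded there. A larger share of reads in the 10 most abundant genes may account for part of it: with depth counted without these genes, 64.6% of the calls were lower, against 75.6% with all genes, a value between the bounds of 60% and 70% set for the test. Median-ratio rescaling centres the differences and so cannot decide between such a shift and a broad fall in transcripts, which stays open.

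Fewer genes were detected in HJ3 than in HJ1, and the transcript pool was narrower. Depth is not the cause of the lower number detected: after thinning every library to 1205215 reads, HJ3 minus HJ1 was -1210 genes, and both HJ3 libraries lay below both HJ1 libraries. Without the 10 most abundant genes of each library the difference at equal depth was still -975 genes, so those genes alone do not account for it. The effective number of genes is another matter: without the 10 most abundant genes, HJ3 stood at 90.4% of HJ1, so these genes may account for most of the narrowing between these 2 groups. That value lies just past the bound of 90% set for it, within the spread of the HJ3 libraries (3044 ± 73.6 against 3369 ± 10.8, SD, n = 2). It does not extend to the other groups, which lay lower still, at 2844 ± 36.2 in HJ2, 2785 ± 33.1 in YL2, 2852 ± 9.82 in JX2 and 2844 ± 29.1 in ZH2, so HJ2 fell below HJ3 and the order of the stages with all genes did not hold. A biological change with ripening stays open.

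In ZH2, 8 genes had 0 reads although each of the 10 other libraries held at least 10 reads of them, among 6931 genes read that deeply in all others. The same rule gave 0 genes for YL2 and for JX2, and 2 for HJ over its 6 libraries. Taken by stage, it gave 7 of 7202 genes for HJ1, although HJ2 and HJ3 of the same cultivar read them. Thus 0 reads under this rule also occurred without a difference of cultivar. The HJ1 genes were weaker cases. At the lowest level of the other libraries they would have had a median of 33.5 reads in HJ1, and at least 15.5. The 8 ZH2 genes would have had a median of 156 reads in ZH2. HJ1 also had 38 further genes with 1 to 10 reads and 109 with 11 to 20. The rule was set after another had been looked at, which asked for at least 3 RPKM in all other libraries and gave 16 genes for ZH2, 2 for JX2, 0 for YL2 and 5 for HJ, so the count depends on the rule. Depth is not the cause, since at the lowest level of the other libraries these genes would have had at least 49.2 reads in ZH2. A graded fall in expression was tested by asking for more genes with 1 to 10 reads than with 0 reads. There were 10 against 8 (two-sided exact binomial p = 0.815). This cannot decide, because neither a graded fall nor its absence predicts an even split. Genes with 0, 1 to 10 and 11 to 20 reads numbered 8, 10 and 19 in ZH2. They numbered 0, 11 and 57 in YL2, and 0, 5 and 109 in JX2, so ZH2 had more at 0. The number at 11 to 20 was lower in groups with deeper libraries, at 9 in HJ2 against 148 in HJ3. The lower number in ZH2, whose libraries were deeper than those of JX2, is therefore not read as a trait of this cultivar. A graded fall stays open. Sequence in ZH2 that is missing, or too different from the reference to be aligned, could also leave these 8 genes without reads and cannot be told apart from lost expression here, because aligned reads were not used.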
